A study of Mus musculus with 6 samples.

How the data were processed

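Single-cell RNA-seq was measured in wounded skin of MaFIA mice, 3 control (vehicle) and 3 depleted (AP20187) samples. Per the labels' protocols, skin was dissociated enzymatically at 37°C for 60 minutes, cells negative for the dead-cell dye propidium iodide were sorted, 18K cells were loaded and libraries were made with the 10x Genomics Chromium 3' version 3 kit. The deposited values are raw UMI counts per gene and cell barcode, made with Cell Ranger 6.0.1 on mouse build mm10, per the submitters' processing notes; the annotation release is not given in the sources used here. The matrices hold 32285 genes and 75166 barcodes, the smallest with 500 UMIs, and no removal of doublets is stated. Samples were grouped by their titles. The labels list sex for each sample and do not say outright that each sample is a different animal, so p-values measure the spread between these samples. Replicate samples differed by more than sampling noise (chi-square per degree of freedom 144 to 905 between pairs), and none was counted with another. The RNA of Xist and Ddx3y matched the labelled sex in all 6 samples.

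Computation used Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, matplotlib 3.10.9) and R 4.3.3 (edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0) with a fixed random seed. Barcodes with fewer than 300 genes or a mitochondrial share of 15% or more were left out. Doublets were scored with Scrublet in scanpy, and the highest scores in each sample were removed at 0.8% per 1000 barcodes, 1045 to 1539 per sample (7569 in all); Scrublet's own threshold would have marked 143 to 507. Counts were scaled per cell, log-transformed and reduced to 30 principal components of 3000 variable genes, leaving out mitochondrial, ribosomal and sex-linked genes, and Leiden clustering at resolution 1 on a graph of 15 neighbours gave 40 clusters. A cluster was called after the class whose fixed markers scored highest if at least 3 were detected and its leading genes over clusters of other candidate classes held no more markers of another class. This naming rule was settled after a first look at the clusters; the markers were fixed earlier. Clusters 21, 25 and 35 stayed unnamed. Fibroblast-like cells were clustered again at resolution 0.5.

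Cells are not replicates, so raw counts were summed per sample and class and tested across samples. A class was tested if every sample had at least 20 of its cells. The main test was edgeR's quasi-likelihood test (glmQLFit with robust estimation, TMM normalization, filterByExpr, no covariate) with Benjamini-Hochberg adjustment over the genes tested in a class and a threshold of 0.05. CPM values are counts scaled to a common library size with TMM, and errors beside them are SDs over 3 samples unless stated. A level quoted from another class beside a gene, without an error, is that gene's share of the summed UMIs of the pooled depleted samples, also as CPM and without TMM. Cell numbers per class were tested with the same model, offset by the cells kept, over the classes with at least 20 cells, and shares also with an exact two-sided permutation test. Fixed gene lists with at least 5 tested members were tested with limma's camera on the edgeR fit, with a preset correlation of 0.01 and, as an alternative, an estimated one, adjusted over the lists in a class. The 25 lists covered matrix, contractile, proliferation, antigen presentation, interferon, chemokine, growth factor, acute-phase, metabolic, dissociation, fibroblast subtype, myeloid, keratinocyte and endothelial genes, and 20 sets of cell type markers served to measure other cells' RNA within a class. The median log2 fold change over all fibroblast-like genes was 0.04.

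For Fcer1g, each cell was thinned at random to 2000 UMIs, leaving out shallower cells, and the share of cells with a UMI was compared between groups, with keratinocyte-like and blood endothelial-like cells as background. Positive and negative fibroblast-like cells were compared with sample as a block in edgeR, with Fcer1g left out of the genes tested and at least 10 cells of each kind per sample. Intervals of shares are exact 95% binomial intervals, and the floor for a count of 0 is 3 counts; both cover counting error only. A fold against 1 to 3 counts is given with an exact counting interval. Gene positions came from a mouse annotation of build mm10, matched by identifier for 85 of 85 named genes.

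Named genes were chosen by a rule fixed before the data were examined: adjusted p under 0.05, no overlap between the replicates of the groups, at least 30 CPM in the higher group and no marker, pan-myeloid or MHC class II gene, then the largest fold changes, up to 10 per direction in fibroblast-like cells and 5 in other classes. Each such gene therefore moves the same way in 3 of 3 samples of a group. Fcer1g, Csf1r and Tyrobp were named in every class tested, up to 4 members with the smallest adjusted p per list, up to 10 genes per direction for the Fcer1g comparison, and the 3 genes with the smallest p where fewer than 5 passed. Markers of other classes quoted beside a list, the list genes Acta2, Col1a1 and H2-Ab1 in some classes and the second use of the rule without depleted replicate 1 were chosen after the data were examined. Some genes that the rule names are not reported here.

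The tests were checked on simulated data with the real means and library sizes and 200 changed genes, drawn among the more abundant genes only. Genes were simulated independently of each other, and no simulated sample stood apart as depleted replicate 1 does. Recovery and false calls in the real data may therefore differ from these values. In fibroblast-like cells (14186 genes) 9% of 100 genes changed 2-fold and 66% of 100 changed 4-fold were recovered with all 6 samples, and 43% and 83% without depleted replicate 1 (14491 genes). The 4-fold figure was 77% in macrophage-like (12200 genes), 74% in neutrophil-like (7353) and 67% in keratinocyte-like cells (14472). Unchanged genes called in the same simulations numbered 4 in fibroblast-like, 9 in fibroblast-like without depleted replicate 1, 13 in macrophage-like, 2 in neutrophil-like and 5 in keratinocyte-like cells. An 8-fold change of 1 of 15 classes was called in 77% of 100 simulated tables. Alternatives fixed before the data were examined were DESeq2 with its size factors, no filter on low counts, sex as a covariate, the replicate number as a block, other cell filters (500 genes and 10%), no doublet removal, Leiden resolutions 0.5 and 2, other thinning depths (1000 and 4000 UMIs, and none), another denominator, subclustering without myeloid genes, leaving out cells with UMIs of 2 or more pan-myeloid genes, and leaving out each sample in turn. Naming clusters by their leading genes over all other cells was added later.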

Results

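The study compared wounded skin with and without macrophages, to find mesenchymal subtypes that depend on macrophages of the acute phase. Its title names Fcer1g+ mesenchymal cells. MaFIA mice (macrophage Fas-induced apoptosis) carry an inducible death receptor driven by the Csf1r promoter, and the dimerizing drug AP20187 kills cells that express it. Live skin cells were sorted from wounds 3 days after injury of mice that were 5 months old. Single-cell RNA-seq libraries (10x Genomics 3' chemistry) were made for 3 vehicle-treated samples (control, 1 female and 2 male) and 3 AP20187-treated samples (depleted, 1 female and 2 male). The control samples held 83279819, 97248351 and 100994632 UMIs (unique molecular identifiers, counted molecules) and the depleted samples 136134901, 133614631 and 115480017. After filtering, 63124 cells remained, 9697 to 11335 per sample, with a median of 5618 to 6646 UMIs per cell in the control and 7171 to 9309 in the depleted samples. Of 40 clusters, 37 could be named from fixed markers and formed 15 classes, and 3.14% ± 0.717 of control and 3.81% ± 0.588 of depleted cells (SD, n = 3 each) stayed in no class.

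The first question was which cells the drug removed. Macrophage-like cells (Csf1r, Adgre1, C1qa) made up 40% ± 5.74 of the control cells and 4.51% ± 4.00 of the depleted cells (SD, n = 3 each), 8.86-fold less. Every depleted sample lay below every control sample, at 0.823%, 3.95% and 8.77% against 46.6%, 36.6% and 36.8%. Dendritic-like cells (led by Cd209a in cluster 17 and Siglech in cluster 40) were 14.3-fold fewer, 4.94% ± 0.0618 against 0.344% ± 0.272, not counting the Ccr7-marked cluster 30. Both classes fell in edgeR's quasi-likelihood test on cell counts, with a log2 fold change of -3.15 (SE 0.823, adjusted p = 0.0234) for macrophage-like cells. The value was -3.84 (SE 0.686, adjusted p = 0.00311) for dendritic-like cells. Adipocyte-like cells rose. There was 1 such cell in the control samples and 1043 in the depleted ones, a ratio of 945 (exact 95% counting interval 169 to 37349, adjusted p = 0.00311). Of these, 870 came from depleted replicate 1, 120 from replicate 2 and 53 from replicate 3. The 0 adipocyte-like cells of control replicates 1 and 2 allow shares of up to 0.0306% and 0.0309%.

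The other 12 classes did not pass. Fibroblast-like cells (Col1a1, Dcn, Pdgfra), the mesenchymal cells of the study's question, were 11.1% ± 3.37 of control and 25.4% ± 6.16 of depleted cells (log2 1.20, SE 0.505, edgeR adjusted p = 0.1004, higher in 3 of 3 samples). Keratinocyte-like cells were 18.8% ± 7.42 against 41.4% ± 5.39 (adjusted p = 0.115). Melanocyte-like cells were 0.659% ± 0.139 against 1.60% ± 0.622 (adjusted p = 0.1004), and basophil-like cells 0.606% ± 0.171 against 0.0737% ± 0.0987 (adjusted p = 0.0802). Neutrophil-like cells, at 11.8% ± 2.99 and 7.18% ± 4.74, overlapped between the groups (adjusted p = 0.354). Shares sum to 100%, so the loss of macrophage-like cells alone raises the other shares. Exact permutation tests of 3 against 3 samples cannot go below p = 0.1, the value for macrophage-like, dendritic-like and adipocyte-like shares. The count of 3 called classes was 1 without control replicate 1 or control replicate 3, and 6 without depleted replicate 1. In those 2 fits without a control sample the macrophage-like (log2 -3.02 and -3.20) and adipocyte-like calls (adjusted p = 0.0519 and 0.0539) were lost. The count was 1 with stricter cell filters, where the macrophage-like call was lost at -3.31 and the dendritic-like call at -1.63 (adjusted p = 0.278). The dendritic-like call was also lost without doublet removal (log2 -1.67, adjusted p = 0.266) and at resolution 2 (log2 -1.67, adjusted p = 0.0551). The count was 1 as well for shares of cells outside the macrophage, dendritic and Langerhans classes.

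**Figure D1:**
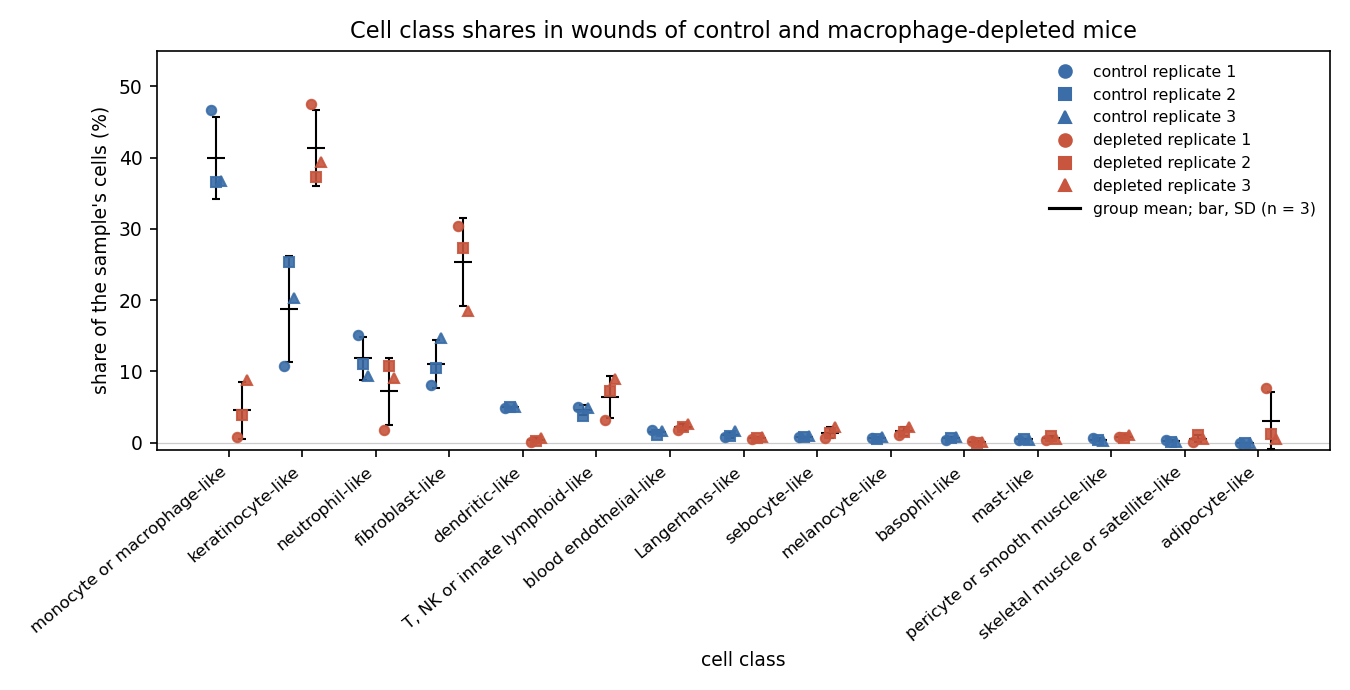
Share of each sample's cells (percent, y axis) in the cell classes (x axis) in control and depleted samples. Points are the 3 samples of each group and bars the mean with its SD; the depleted samples lie at 0.823% to 8.77% for macrophage-like cells, below every control sample.

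In fibroblast-like cells the drug-treated samples had more Igfbp3 and Galnt15 RNA and less RNA of MHC class II genes. Igfbp3, a secreted binding protein of insulin-like growth factors, was 64.7 ± 8.21 normalized counts (CPM) in the control and 737 ± 244 in the depleted samples (log2 3.51, SE 0.288, adjusted p = 0.0169, n = 3 each). Galnt15, a member of the family that starts mucin-type O-glycosylation, rose from 20.3 ± 2.53 to 178 ± 55.7 CPM (log2 3.13, SE 0.283, adjusted p = 0.0249). Ifitm1, an interferon-inducible membrane protein, rose from 96.1 ± 14.1 to 522 ± 135 CPM (log2 2.44, SE 0.250, adjusted p = 0.0385), while the pooled neutrophil-like cells of the depleted samples held 15934 CPM of it. Wfdc21, chosen after its values were seen, rose from 1.69 ± 0.510 to 13.6 ± 1.90 CPM (adjusted p = 0.0286). On mouse build mm10, Igfbp3 (ENSMUSG00000020427) lies on the minus strand of chromosome 11 at 7206086 to 7213923. Galnt15 (ENSMUSG00000021903) lies on the plus strand of chromosome 14 at 32028989 to 32062197 and Ifitm1 (ENSMUSG00000025491) on the plus strand of chromosome 7 at 140967221 to 140969825. All are annotated as protein-coding genes.

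The 4 genes that fell were all members of the MHC class II list, the genes for presenting antigen to CD4 T cells. Cd74, the invariant chain, fell by 2.94 on the log2 scale (SE 0.240, adjusted p = 0.0169), from 51.4 ± 9.07 to 6.71 ± 1.57 CPM. H2-Aa fell by 2.82 (SE 0.208, adjusted p = 0.0161), from 28.5 to 4.03 CPM. H2-Ab1 and H2-Eb1 followed at 30.01 against 5.47 and 22.7 against 4.15 CPM. Counts of H2 genes are uncertain because the genes are alike in sequence. Of 6 list members tested, 0 rose and 4 fell over all genes, and 5 fell when adjusted over the list alone. Camera called the list lower (median log2 -2.45, adjusted p = 1.2e-29; adjusted p = 0.0942 with an estimated correlation). Macrophage markers measured in the same fibroblast-like cells had a median log2 of -1.52 (14 tested, 0 called), and Cd74 stood at 4325 ± 388 CPM in the control macrophage-like cells. Cd74 also went from 64.2 to 8.21 CPM in sebocyte-like (log2 -2.88) and from 61.2 to 6.74 CPM in melanocyte-like cells (log2 -3.01). It did not pass in these classes (edgeR adjusted p = 0.350 and 0.327). A fall of this size was thus not particular to fibroblast-like cells.

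These 8 genes were all that passed among 14186 tested in fibroblast-like cells (edgeR, 4 higher and 4 lower). There were 2218 genes at an unadjusted p under 0.05 and 809 called by DESeq2, 14 without a filter on low counts, and 5 when cells with UMIs of 2 or more pan-myeloid genes were left out, a filter that removed a larger share of the control cells. Depleted replicate 1 set much of this number. Its fibroblast-like cells lay in clusters 8 and 26 (77.6% and 22.0%), whereas clusters 6, 14, 16 and 19 held most of the class in the control samples and in depleted replicates 2 and 3. Without depleted replicate 1 the count was 503 (300 higher and 203 lower), and all 8 genes were among them. It was 35 without depleted replicate 3 and 0 without control replicate 1, 2 or 3 or depleted replicate 2. Libraries of this class held 14012171 to 37760000 UMIs.

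The genes that passed without depleted replicate 1 were named by the same rule, a choice made after the data were examined (3 control against 2 depleted samples). Lcn2, an iron-scavenging acute-phase protein, was 102 CPM in the control and 1395 in depleted replicates 2 and 3 (log2 3.76, adjusted p = 0.0416), and 3694 in depleted replicate 1. Cxcl13, a B cell chemokine and a leading gene of fibroblast cluster 8, was 234 against 3526 CPM (log2 3.91, SE 0.496, adjusted p = 0.0291), and 10811 in depleted replicate 1. Fmo2, a flavin-containing monooxygenase, was 12.97 against 87.2 CPM (log2 2.74, adjusted p = 0.00879). Saa1, an acute-phase protein with near-identical relatives and so uncertain counts, was 12.3 against 59.3 (log2 2.27, adjusted p = 0.0389). Lrg1 was 6.70 against 41.9 (log2 2.64, adjusted p = 0.0389). Tmem176b (log2 2.07) was higher as well. Reg1 was 14.6 against 64.2 CPM (log2 2.13, adjusted p = 0.0368) but 1.82 in depleted replicate 1. Lower was the contractile gene Acta2, the smooth muscle actin of myofibroblasts (301 against 99.8 CPM, log2 -1.60, adjusted p = 0.0438, and 12.6 in depleted replicate 1). Myl9 was lower too (44.0 against 12.3, log2 -1.85, adjusted p = 0.0359). The matrix gene Col8a1 was lower (86.4 against 29.4 CPM, log2 -1.55, adjusted p = 0.0360), as were the growth factor Ereg (log2 -1.65) and the chemokine Ccl9 (log2 -1.51). The proliferation genes were lower as well, Top2a (60.6 against 20.6 CPM, log2 -1.56, adjusted p = 0.0408), Mki67 (log2 -1.54), Cdk1 (log2 -1.57), Ube2c (log2 -1.56) and Rrm2 (log2 -1.63). Over all 6 samples Lcn2, Cxcl13, Acta2 and Top2a did not pass (adjusted p = 0.123, 0.123, 0.243 and 0.144).

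**Figure D2:**
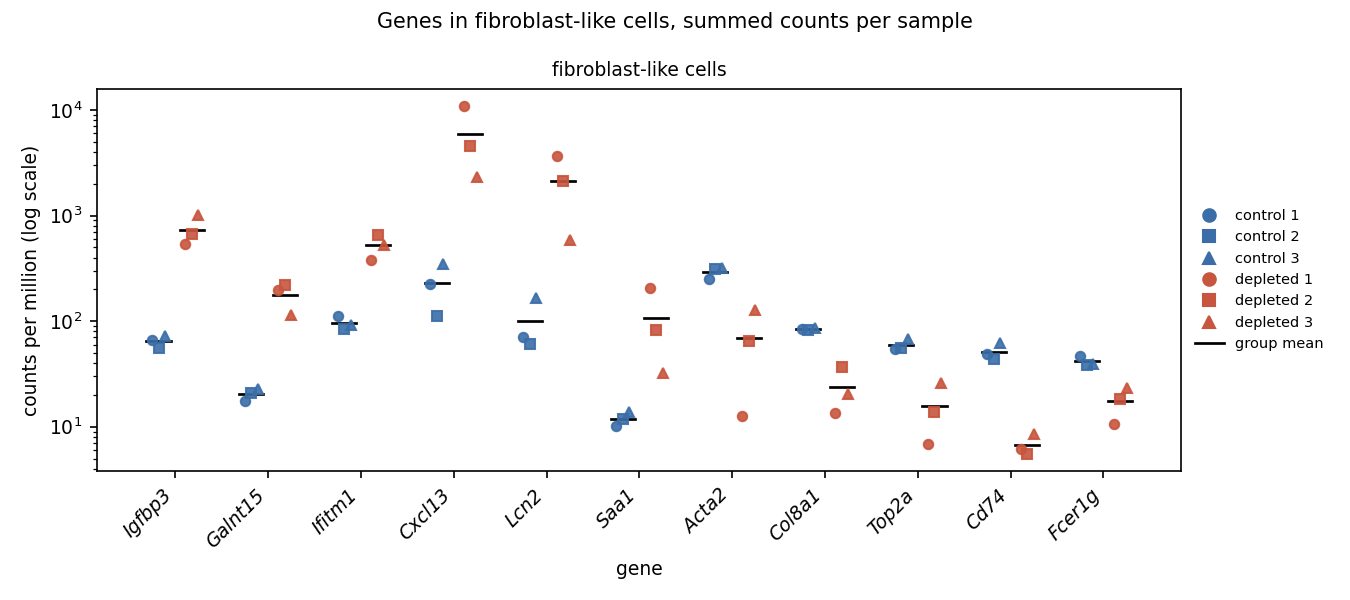
Normalized counts (CPM, y axis, log scale) of named genes (x axis) summed over fibroblast-like cells, 1 point per sample (3 control, 3 depleted), black lines group means. Igfbp3, Galnt15 and Ifitm1 are higher and Cd74 is lower in all depleted samples; Acta2 is 12.6 CPM and Cxcl13 10811 CPM in depleted replicate 1.

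Among the fixed gene lists, proliferation genes stood lower as a group in fibroblast-like cells. Of 24 cell cycle genes 0 passed over all genes and 20 fell when adjusted over the list alone (median log2 -1.70). Among them were Nusap1 of the mitotic spindle (log2 -1.50), Rrm2 for nucleotide supply (log2 -1.66) and the replication helicase genes Mcm2 (log2 -1.15) and Mcm5 (log2 -1.23). Camera called the list (adjusted p = 7.3e-25; adjusted p = 0.166 with an estimated correlation). Of 17 myofibroblast and contractile genes, 0 passed over all genes and 5 fell when adjusted over the list alone, led by Myl9 (log2 -2.10), Tpm1 (log2 -1.01) and Cnn2 (log2 -1.68). Camera called this list (median log2 -1.05, adjusted p = 1.25e-11; adjusted p = 0.166 with an estimated correlation). Of 22 matrix structure genes, 0 passed over all genes and 1, Col8a1, fell when adjusted over the list alone (median log2 -0.68, camera adjusted p = 5.3e-07; adjusted p = 0.439 with an estimated correlation). The median of the matrix list was -0.33 without depleted replicate 1, where Col1a1, the main fibrillar collagen gene, was 698 CPM against a control mean of 12559. Of 19 collagen processing genes 0 passed in either count (median log2 -0.56, camera adjusted p = 1.1e-06; adjusted p = 0.287 with an estimated correlation).

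Complement and acute-phase genes stood higher. Of 14, 0 passed over all genes and 6 rose when adjusted over the list alone (median log2 0.96, camera adjusted p = 3.4e-09; adjusted p = 0.166 with an estimated correlation). They included Lcn2 (log2 4.42), the complement factor and adipokine Cfd (log2 7.52) and haptoglobin, Hp (log2 2.53). Adipocyte markers in the same fibroblast-like cells had a median log2 of 4.92 (3 tested, 0 called). Of 23 keratinocyte wound activation genes, 10 rose and 1 fell when adjusted over the list alone and 0 passed over all genes (median log2 0.76, camera adjusted p = 3.8e-06; adjusted p = 0.166 with an estimated correlation). Of 8 keratinocyte differentiation genes 6 rose when adjusted over the list alone and 0 over all genes (median log2 1.52, camera adjusted p = 8.9e-06; adjusted p = 0.108 with an estimated correlation). Keratinocyte markers moved with both lists (13 tested, 0 called, median log2 2.25), Krt14 from 45.8 to 243 CPM and Krt5 from 18.3 to 93.5.

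Pan-myeloid genes stood lower in fibroblast-like cells. Of 22, 1 (Cd74) fell over all genes and 10 when adjusted over the list alone (median log2 -1.23, camera adjusted p = 7.4e-18; adjusted p = 0.166 with an estimated correlation). Fc receptor gamma chain partners gave 0 of 14 over all genes and 6 lower when adjusted over the list alone (median log2 -1.26, camera adjusted p = 4.55e-09; adjusted p = 0.185 with an estimated correlation). They were led by Clec4e, Fcer1g, Trem2 and Fcgr1. Camera also called growth factor, macrophage repair, macrophage inflammatory, glycolysis and dissociation response genes, with 0 members past the threshold over all genes. Adjusted over the list alone, 5 of 27 growth factor, 4 of 17 repair and 3 of 18 inflammatory genes fell (adjusted p = 0.166, 0.201 and 0.185 with an estimated correlation). For glycolysis and hypoxia it was 0 of 22 and for the dissociation response 1 of 19 higher (adjusted p = 0.668 and 0.543 with an estimated correlation). In all, 15 of 25 lists were called, and 0 with an estimated correlation. Not called were matrix proteases (camera adjusted p = 0.316), chemokines (0.658), interferon response (0.316), MHC class I (0.760), fascia (0.568) and papillary fibroblast genes (0.310). The same held for resident macrophage (0.456), recruited monocyte (0.316), neutrophil activation (0.717) and endothelial activation genes (0.362).

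Fcer1g encodes the common gamma chain of Fc receptors (ENSMUSG00000058715, chromosome 1, 171229572 to 171234365, minus strand, protein-coding), and the study's title places it in mesenchymal cells. After thinning each cell to 2000 UMIs, 5.68% ± 0.657 of control and 3.28% ± 1.47 of depleted fibroblast-like cells had an Fcer1g UMI (SD, n = 3 each; unthinned 27.6% ± 6.72 and 15.5% ± 6.12). Every depleted sample, at 1.76%, 3.38% and 4.69%, lay below the control samples at 6.43%, 5.41% and 5.20%. The difference of -2.41 percentage points had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 samples allow. It was -5.91 points when doublets were not removed and -4.47 at 4000 UMIs. When cells with UMIs of 2 or more pan-myeloid genes were left out, the difference was 0.403 points and that of the log2 ratio to keratinocyte-like cells 0.29. That filter selects on myeloid RNA itself and kept 173 of 762, 422 of 961 and 522 of 1480 control against 2936 of 3296, 1667 of 2781 and 1212 of 2027 depleted cells, so the turned direction is not read as a change. Thinning left out 142 control and 291 depleted fibroblast-like cells with under 2000 UMIs. In the sums over fibroblast-like cells Fcer1g was 41.6 ± 4.61 against 17.5 ± 6.46 CPM (log2 -1.25, SE 0.291, edgeR adjusted p = 0.144, lower in 3 of 3 samples). The macrophage receptor gene Csf1r (log2 -0.98, adjusted p = 0.172) and the signalling adaptor gene Tyrobp (log2 -1.64, adjusted p = 0.189) did not pass either.

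The same measure in cells not known for Fcer1g gave 4.76% ± 1.60 of control and 3.35% ± 1.23 of depleted keratinocyte-like cells (exact permutation p = 0.3, unthinned 22.4% and 13.8%). It gave 5.85% ± 2.78 against 3.68% ± 2.27 of blood endothelial-like cells (exact permutation p = 0.5, unthinned 20.6% and 11.4%). Macrophage-like cells had it in 99.0% and 99.2%. Within samples, the fibroblast-like share over the keratinocyte-like share was 1.04, 1.79 and 1.02 in the control and 0.860, 0.968 and 1.04 in the depleted samples. Fisher's exact test separated fibroblast-like from keratinocyte-like cells in control replicate 2 (adjusted p = 0.00962) and in no other sample (adjusted p = 0.878). The log2 ratio was 0.31 ± 0.461 in the control and -0.07 ± 0.139 in the depleted samples (exact permutation p = 0.2). Whether the share lay above that of keratinocyte-like cells differed between the depths, each a single random draw, in tests within samples chosen after the data were examined. At 1000 UMIs it was higher in 3 of 3 control samples, at 5.42%, 4.05% and 4.15% against 2.89%, 1.68% and 2.36% (Fisher's exact test, adjusted p = 0.0147, 0.000537 and 0.00764), and in 0 depleted samples (lowest adjusted p = 0.395). The log2 ratio was then 0.9985 ± 0.241 and -0.14 ± 0.167 (exact permutation p = 0.1). At 4000 UMIs no sample passed (lowest adjusted p = 0.260). Fcer1g without thinning was 51.2, 41.1 and 40.2 CPM in control fibroblast-like cells and 48.0, 21.3 and 26.4 in control keratinocyte-like cells. In the draw at 1000 UMIs it was 60.6, 48.6 and 50.1 against 37.6, 18.0 and 24.5 CPM. That draw thus lay above the unthinned level in fibroblast-like and below it in keratinocyte-like cells. The difference at 1000 UMIs therefore holds noise of the draw and is not read as an effect of depth. Median depths before thinning were 12649 to 15774 UMIs in control and 9371.5 to 11590 in depleted fibroblast-like cells, against 9569 to 11640 and 8499 to 10313 in keratinocyte-like cells.

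**Figure D3:**
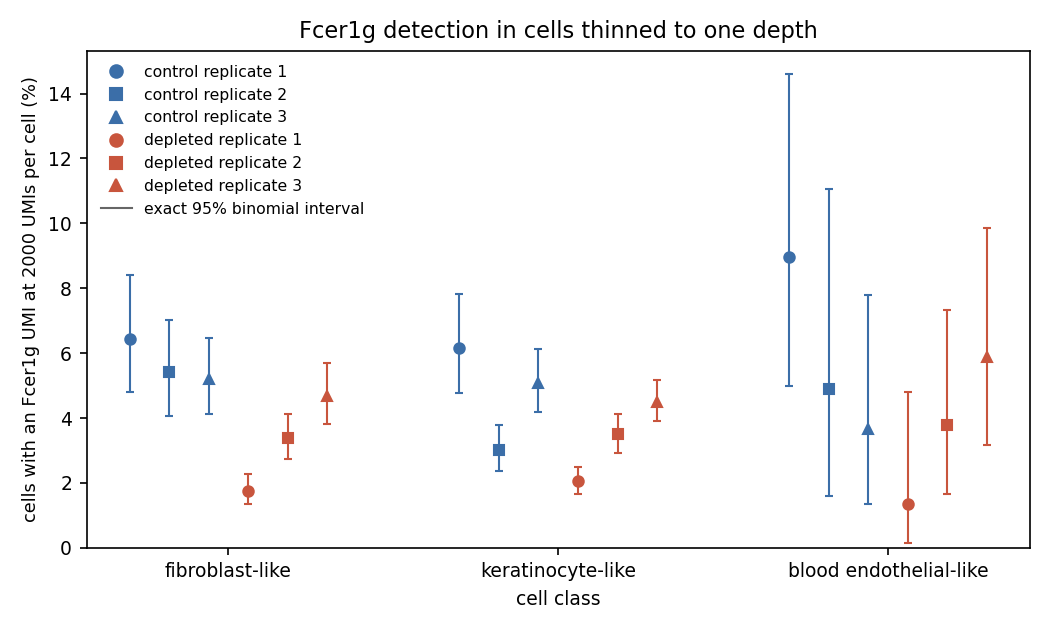
Share of cells with an Fcer1g UMI (percent, y axis) after thinning to 2000 UMIs, per sample (x axis), in fibroblast-like, keratinocyte-like and blood endothelial-like cells. Points are samples and bars exact 95% binomial intervals; fibroblast-like cells stand at 1.76% to 6.43% and lie close to keratinocyte-like cells except in control replicate 2.

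Fibroblast-like cells with an Fcer1g UMI held more RNA of some other myeloid genes. Comparing 425 positive with 10882 negative cells within the 6 samples (sample as a block), 18 of 7169 genes were higher and 3 lower in positive cells (edgeR). Il1b, the inflammatory cytokine, was 107.5 ± 104.76 against 10.3 ± 6.62 CPM (log2 3.20, SE 0.292, adjusted p = 2.4e-13). The MHC class II gene H2-Aa was 92.7 against 10.9 (log2 2.90, adjusted p = 0.0261), the leukocyte surface gene Cd52 88.4 against 10.6 (log2 2.86, adjusted p = 3.9e-10) and the complement gene C1qb of macrophages 61.8 against 10.3 (log2 2.42, adjusted p = 2.2e-06). H2-Eb1, H2-Ab1, C1qc, Alox5ap, Pf4 and Chil3 were higher too (log2 2.03 to 2.66). Of 8 pan-myeloid genes tested 4 were higher, with a median log2 of 2.53. Lower by small amounts was the matrix proteoglycan gene Bgn (log2 -0.32, adjusted p = 0.00466). So were Serpina3n (log2 -0.37, adjusted p = 0.00172, with close relatives and uncertain counts) and Ctla2a (log2 -0.37, adjusted p = 0.0261). In the control samples 46.6% of 178 positive cells and 5.39% of 3025 negative cells held UMIs of at least 2 other pan-myeloid genes, and Col1a1 was seen in 99.4% and 98.9%. In the depleted samples the myeloid co-detection was 10.1% of 247 against 2.16% of 7857 cells, with single genes at 4.45% against 1.51% (Tyrobp), 3.24% against 2.28% (Lyz2), 1.21% against 1.22% (C1qa) and 0.810% against 0.827% (Csf1r). The same genes in the control samples stood at 28.1% against 2.84%, 28.1% against 7.34%, 11.8% against 2.05% and 7.87% against 3.01%. In the depleted samples Col1a1 was seen in 81.8% against 73.6% and the neutrophil gene S100a9 in 42.1% against 34.7%. When cells with UMIs of 2 or more pan-myeloid genes were left out, 0 of 5286 genes were higher and 5 lower by edgeR (63 higher at an unadjusted p under 0.05; no other tool was run). That fit had 5 samples and 185 positive cells, and its filter removes the myeloid RNA that is compared, so the 0 does not show that no gene differs. The count of higher genes was 7 without control replicate 3, 11 without control replicate 2 and 29 without depleted replicate 2. That of lower genes was 1 without control replicate 2 and 6 without depleted replicate 3. When doublets were not removed, 381 genes were higher and 249 lower.

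Clustering the fibroblast-like cells alone gave 12 subclusters, and 0 differed in share between the groups (edgeR, 3 at an unadjusted p under 0.05, and 1 called when clusters were named over all other cells; no other tool was run). Those 3 were nearly all cells of depleted replicate 1: 1406 of 1407 cells of subcluster 3 (led by Cxcl13, Mcoln2 and Csf3), 1151 of 1155 of subcluster 6 (Il1rl1, Slco2a1) and 707 of 711 of subcluster 10 (Il19, Ctla2a). Without depleted replicate 1, 3 subclusters passed. Subcluster 4, led by the proliferation genes Pclaf, Ube2c and Birc5, was 27.9% ± 2.60 of control fibroblast-like cells and 3.25% and 9.77% in depleted replicates 2 and 3 (log2 -2.10, adjusted p = 0.00564). Subcluster 12, led by keratin genes such as Krt15 and Krt5, was larger (log2 1.96, adjusted p = 0.0206). Subcluster 11 (142 cells) was led by the myeloid genes Lyz2, Cd74, Tyrobp and Fcer1g, with Fcer1g UMIs in 92.3% of its cells. It made up 3.25% ± 0.250 of control fibroblast-like cells and 0.349% and 1.10% in depleted replicates 2 and 3 (log2 -2.19, adjusted p = 0.00564). With depleted replicate 1, which had 0 cells of it, it did not pass (log2 -2.75, adjusted p = 0.720). Of the 10 leading genes, 8 (subcluster 11), 9 (subcluster 12) and 5 (subcluster 4) themselves differed between the groups without depleted replicate 1. These sizes are therefore not read as changes of cell type. When myeloid genes and markers of other classes were kept out of the subclustering, a subcluster led by Lyz2, Cd74 and Tyrobp formed again. It held 112 cells, 97.3% of them with Fcer1g UMIs, and did not pass over all 6 samples (log2 -3.11, edgeR adjusted p = 0.553).

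The macrophage-like cells that remained after depletion differed widely from those of the control samples, with 511 of 12200 genes called (266 higher and 245 lower, edgeR, n = 3 each). Cd209b, a C-type lectin receptor of tissue macrophages, rose from 5.33 ± 2.76 to 177 ± 71.1 CPM (log2 5.09, SE 0.449, adjusted p = 0.0025), and no other class held more than 1.39 CPM of it in the depleted samples. Vegfa, the main angiogenic growth factor, fell from 170 ± 67.2 to 15.9 ± 7.28 CPM (log2 -3.31, SE 0.420, adjusted p = 0.00726). Axl, a receptor for the uptake of dying cells, fell from 42.3 ± 6.76 to 7.38 ± 4.602 CPM (log2 -3.00, adjusted p = 0.00381). Fcrls (log2 -2.71), the matrix crosslinker Tgm2 (log2 -2.67) and Spon1 (log2 -3.40) fell as well. Lcn2 rose from 9.81 ± 5.40 to 594 ± 174 CPM (log2 5.91, SE 0.455, adjusted p = 0.0025), and Cd55, a complement inhibitor, from 2.24 to 79.1 (log2 5.13). Cxcl13 (1.12 to 807 ± 1056 CPM, log2 9.45) and Cfd (0.229 to 44.2 CPM, log2 6.90) rose with them. In the depleted samples Cxcl13 was 5664 CPM in fibroblast-like and Cfd 17672 and Lcn2 17259 CPM in adipocyte-like cells. Fcer1g itself was 3614 ± 256 against 3571 ± 1198 CPM (log2 -0.02, adjusted p = 0.979). Csf1r (log2 -0.69, adjusted p = 0.259) and Tyrobp (log2 -0.92, adjusted p = 0.114) did not pass.

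Antigen presentation genes were lower in macrophage-like cells. Of 7 MHC class II genes 7 fell over all genes and adjusted over the list alone (median log2 -3.23, camera adjusted p = 3.9e-19; adjusted p = 0.170 with an estimated correlation). Cd74 was 4325 ± 388 against 458 ± 221 CPM and H2-Ab1 1490 against 151. Of 15 MHC class I pathway genes 4 fell over all genes, B2m (log2 -0.79) and H2-K1 (log2 -0.74) among them, and 12 adjusted over the list alone (median log2 -0.81; adjusted p = 0.1799 with an estimated correlation). Of 22 interferon response genes 2 fell over all genes and 15 adjusted over the list alone (median log2 -0.93; adjusted p = 0.170 with an estimated correlation), led by Ifit2 (log2 -1.52). Of 12 resident macrophage genes 7 rose over all genes and 10 adjusted over the list alone (median log2 1.18; adjusted p = 0.170 with an estimated correlation). They included Lyve1, a hyaluronan receptor (45.1 to 746 CPM, log2 4.04, adjusted p = 0.00726), and the haemoglobin scavenger receptor Cd163 (61.8 to 384 CPM, log2 2.63). Of 20 macrophage repair genes 1 rose and 4 fell over all genes, and 3 rose and 10 fell adjusted over the list alone (median log2 -1.08; adjusted p = 0.1799 with an estimated correlation). Of 11 complement and acute-phase genes 6 rose over all genes, and 7 rose and 1 fell adjusted over the list alone (median log2 1.78; adjusted p = 0.1799 with an estimated correlation). Adipocyte markers rose alongside (2 of 2 tested, median log2 4.40), as did 4 of 13 keratinocyte markers (median log2 1.82). Recruited monocyte genes gave 0 of 12 over all genes and 2 lower adjusted over the list alone (median log2 -1.08; adjusted p = 0.500 with an estimated correlation).

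In total 14 of 25 lists were called in macrophage-like cells and 0 with an estimated correlation. The 7 called lists not described above had adjusted p = 0.170 to 0.598 with an estimated correlation. Different clusters held most macrophage-like cells: cluster 1 held 40.1%, 44.2% and 41.4% of the control class against 0%, 9.66% and 19.3%. Cluster 9 held 16.6%, 11.5% and 20.1% against 73.1%, 59.9% and 35.7%. The 93 macrophage-like cells of depleted replicate 1 gave 384298 UMIs. The count of 511 genes was 1128 without depleted replicate 1, 47 without depleted replicate 2, 306 without depleted replicate 3, and 130, 265 and 243 without control replicates 1, 2 and 3. DESeq2 called 805, and the count was 783 without a filter on low counts and 1107 at clustering resolution 0.5.

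**Figure D4:**
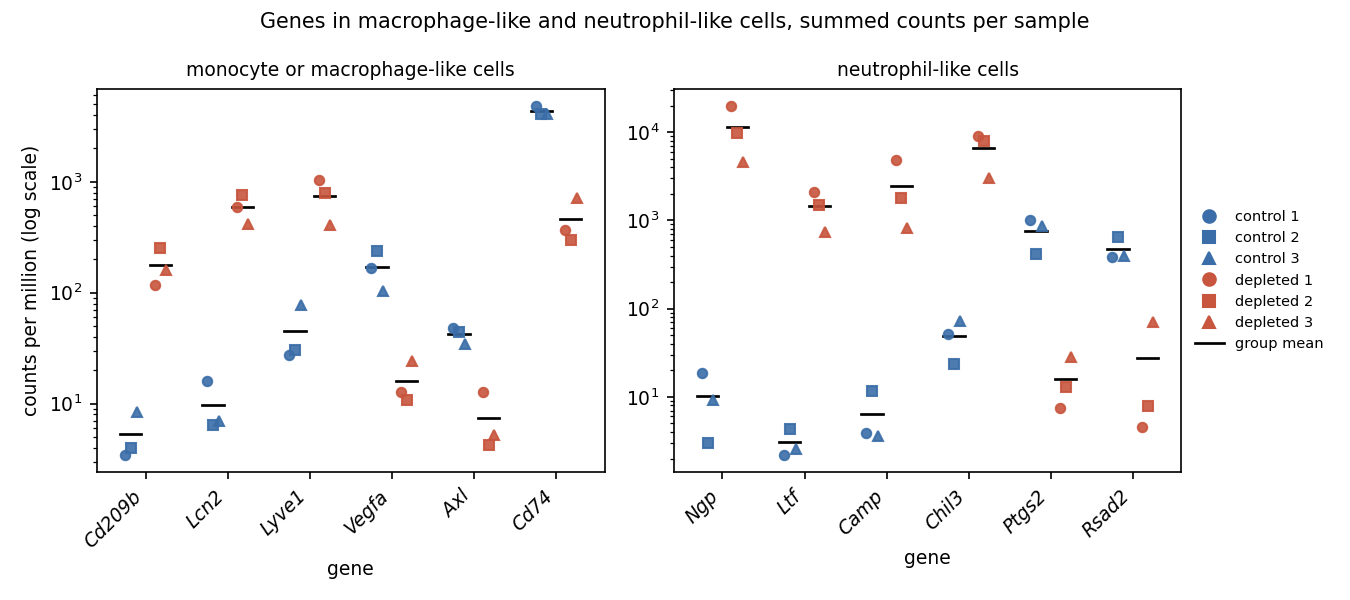
Normalized counts (CPM, y axis, log scale) of named genes (x axis) in macrophage-like and neutrophil-like cells, 1 point per sample (3 control, 3 depleted), black lines group means. Cd209b and Lyve1 are higher and Vegfa, Axl and Cd74 lower in macrophage-like cells of all depleted samples, and Ngp, Ltf, Camp and Chil3 higher and Ptgs2 and Rsad2 lower in their neutrophil-like cells.

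Neutrophil-like cells showed the most called genes, 2057 of 7353 (1029 higher and 1028 lower, edgeR, n = 3 each). The genes with the largest rises included Ltf, Ngp and Camp, which are known from granules that neutrophils form in the marrow. Ltf, lactoferrin, went from 3.04 ± 1.14 to 1443 ± 693 CPM (log2 8.90, SE 0.621, adjusted p = 0.00223). Ngp went from 10.4 ± 7.93 to 11366 ± 7633 (log2 10.06, SE 0.987, adjusted p = 0.00258) and Camp, the cathelicidin, from 6.39 ± 4.6015 to 2477 ± 2094 (log2 8.60, adjusted p = 0.00296). Chil3, a chitinase-like secreted protein, rose from 49.4 ± 24.7 to 6684 ± 3191 CPM (log2 7.08). The ficolin gene Fcnb had 1 count in the control and 374 in the depleted samples (ratio 142, exact 95% counting interval 25.4 to 5630, adjusted p = 0.00837). Ptgs2, the inducible prostaglandin synthase, fell from 768 ± 311 to 16.1 ± 10.6 CPM (log2 -5.55, SE 0.620, adjusted p = 0.00296), and the antiviral gene Rsad2 from 478 ± 147 to 27.4 ± 36.9 (log2 -4.10, adjusted p = 0.0191). The phosphatase gene Dusp2 (log2 -4.61), the potassium channel gene Kcnj2 (log2 -3.99) and AW011738 (log2 -5.46) fell too. Ngp and Camp are among the leading genes of cluster 12, which held 99.5%, 99.7% and 95.4% of the class in the depleted samples. Cluster 5 held 99.1%, 99.7% and 99.0% in the control samples, so these genes also define the clusters. Fcer1g (log2 -0.24, adjusted p = 0.573), Csf1r (log2 -1.88, adjusted p = 0.0541) and Tyrobp (log2 -0.75, adjusted p = 0.146) did not pass.

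Of 23 neutrophil activation and ageing genes 4 rose and 10 fell over all genes, and 4 rose and 13 fell adjusted over the list alone (median log2 -1.88, mean -0.29; adjusted p = 0.521 with an estimated correlation). The marrow homing receptor gene Cxcr4 fell from 471 to 48.5 CPM (log2 -3.27). Of 19 dissociation and early response genes 11 fell over all genes and 12 adjusted over the list alone (median log2 -1.64; adjusted p = 0.639 with an estimated correlation). Among them were Egr1 (554 to 59.1 CPM, log2 -3.23) and Zfp36 (log2 -2.91). Of 20 interferon response genes 5 fell in both counts (median log2 -1.75; adjusted p = 0.639 with an estimated correlation), including Isg15 (log2 -3.26) and Irf1 (log2 -1.52). Of 9 complement and acute-phase genes 7 rose over all genes and 8 adjusted over the list alone (median log2 1.87; adjusted p = 0.321 with an estimated correlation), Lcn2 from 1217 to 18164 CPM (log2 3.90). MHC class II genes fell (4 of 5 over all genes, 5 adjusted over the list alone, median log2 -2.58; adjusted p = 0.321 with an estimated correlation). Keratinocyte markers rose in the same cells (7 of 13, median log2 1.36), and 5 of 14 keratinocyte wound activation genes rose in both counts (median log2 1.15; adjusted p = 0.321 with an estimated correlation).

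In total 12 of 22 lists were called in neutrophil-like cells and 0 with an estimated correlation. The 6 called lists not described above had adjusted p = 0.521 to 0.723 with an estimated correlation. Cells differed in depth, with median UMIs of 1715.5, 1429 and 1343 in the control and 9526, 7969 and 4308 in the depleted samples. The count of 2057 genes was 3419 without depleted replicate 1, 1008 without depleted replicate 2, and 566, 920 and 866 without control replicates 1, 2 and 3. It was 513 when doublets were not removed, and DESeq2 called 2307.

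In keratinocyte-like cells 0 of 14472 genes passed (edgeR, n = 3 each), with 1750 at an unadjusted p under 0.05 and 227 called by DESeq2. The count was 10 without depleted replicate 1, 1 without depleted replicate 3, 2 without a filter on low counts and 1 with sex as a covariate. The 3 smallest p-values belonged to genes that were higher in 3 of 3 depleted samples. Serpina3j had 3 counts against 1129 (ratio 176, exact 95% counting interval 60.2 to 857, adjusted p = 0.210, counts uncertain among near-identical relatives). Ngp was 0.293 against 12.1 CPM (adjusted p = 0.210), and 7818 CPM in the pooled neutrophil-like cells of the depleted samples. Il22ra2, a soluble receptor that binds interleukin 22, was 5.18 ± 1.46 against 50.3 ± 19.6 CPM (log2 3.28, adjusted p = 0.232). Camera called 10 of 25 lists and 0 with an estimated correlation (adjusted p = 0.614 for each). Complement and acute-phase genes stood highest (0 of 12 over all genes, 9 higher adjusted over the list alone, median log2 2.32; adjusted p = 0.614 with an estimated correlation), led by Hp, Cfd, Lcn2 and Serping1. The other higher lists were fascia (12 genes, 4 higher adjusted over the list alone, median log2 0.77), wound activation (28 and 1, 0.75), chemokines (23 and 3, 0.52, with Cxcl1 at 40.7 against 111 CPM), neutrophil activation (22, 2 higher and 1 lower, 0.45) and glycolysis (22 and 0, 0.33). The lower ones were cell cycle (24 and 0, -0.55), MHC class II (7 and 0, -0.63), pan-myeloid (22 and 2, -0.88) and Fc receptor genes (14 and 0, -0.98), and 0 members of these lists passed over all genes. Macrophage markers in the same keratinocyte-like cells had a median log2 of -1.11 and neutrophil markers 1.13. S100a8 was 9968 CPM in depleted replicate 1 against 492 and 366 in replicates 2 and 3. Clusters 7 and 10 held 47.8% and 43.2% of the class in depleted replicate 1, while clusters 2, 4 and 13 held most in the other samples. Without depleted replicate 1, 6 lists were called. A test of whether any gene changed differently in fibroblast-like than in keratinocyte-like cells called 0 of 14157 (edgeR, 3473 at an unadjusted p under 0.05; no other tool was run).

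Blood endothelial-like cells had 31 called genes of 9590 (21 higher and 10 lower, edgeR, n = 3 each). Apln, the apelin peptide of sprouting endothelium, fell from 126 ± 29.4 to 20.7 ± 10.5 CPM (log2 -2.61, SE 0.345, adjusted p = 0.0228), and Prnd from 74.9 ± 31.9 to 11.7 ± 1.76 (log2 -2.66, adjusted p = 0.0228). Cxcr4, the receptor of Cxcl12, fell from 80.6 ± 28.3 to 19.6 ± 4.08 (log2 -2.04, adjusted p = 0.0274). Cd276 (log2 -2.19) and Akr1b8 (log2 -1.67) fell as well. Timp4, an inhibitor of matrix metalloproteinases, rose from 8.22 ± 5.00 to 103 ± 44.5 CPM (log2 3.62, adjusted p = 0.0228). The acute-phase genes Serpina3n (7.58 to 220 CPM, log2 4.76, SE 0.642, adjusted p = 0.0251) and Saa3 (log2 4.09, adjusted p = 0.0429) rose, both with close relatives and uncertain counts. Dmkn (log2 2.91) and Rarres2 (log2 2.40) rose too. Each of the named genes that rose stood higher in another class of the depleted samples. Adipocyte-like cells held 1713 CPM of Serpina3n and 17487 of Saa3, and pericyte-like cells 438 of Timp4. Keratinocyte-like cells held 1895 CPM of Dmkn and fibroblast-like cells 2760 of Rarres2. Fcer1g did not pass (29.9 against 22.4 CPM, adjusted p = 0.739). The count of 31 was 132 without depleted replicate 1, 50 without depleted replicate 3, 6 without control replicate 1 and 0 without control replicate 2 or 3. DESeq2 called 163, and the count was 457 without a filter on low counts and 55 when doublets were not removed.

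Of 23 endothelial activation and angiogenesis genes 0 rose and 2 fell over all genes, Apln and Cxcr4, and 4 fell adjusted over the list alone (median log2 -0.19; adjusted p = 0.399 with an estimated correlation). Of 24 cell cycle genes 0 passed over all genes and 2 fell adjusted over the list alone (median log2 -0.97, camera adjusted p = 8.1e-12; adjusted p = 0.346 with an estimated correlation). Complement and acute-phase genes (0 of 9 over all genes, 5 higher adjusted over the list alone, median log2 1.47), chemokines (1 of 16, 4, 1.09) and interferon response genes (0 of 22, 5, 0.69) stood higher, with adjusted p = 0.0792, 0.0792 and 0.199 with an estimated correlation. Keratinocyte markers rose in the same cells (4 of 12, median log2 2.77, Krt14 from 36.4 to 227 CPM) and lymphatic markers too (2 of 6, median log2 2.57). In total 12 of 22 lists were called and 0 with an estimated correlation. The 7 called lists not described above had adjusted p = 0.177 to 0.467 with an estimated correlation. All cells of the class came from cluster 20.

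Langerhans-like cells, named after the antigen-presenting cells of the epidermis, made up 1.09% ± 0.436 of control and 0.601% ± 0.136 of depleted cells (edgeR adjusted p = 0.217). Their only cluster, 30, was led by Cd207 and H2-M2 and also by the fixed dendritic markers Ccr7, Ccl22 and Il4i1. In this class 2 of 5 Langerhans markers rose (median log2 0.98) and 1 of 6 dendritic markers fell (median log2 -0.25). A changed mix of cells is therefore not told apart from changed expression. The class had 198 called genes of 5569 (50 higher and 148 lower, edgeR, n = 3 each). Of 13 interferon response genes 6 fell over all genes and 11 adjusted over the list alone (median log2 -1.36, camera adjusted p = 2.4e-14; adjusted p = 0.0532 with an estimated correlation). Among them were Ifi27l2a (294 to 24.4 CPM, log2 -3.59) and Gbp2 (log2 -2.69). Of 15 MHC class I pathway genes 3 fell over all genes and 9 adjusted over the list alone (median log2 -0.83; adjusted p = 0.181 with an estimated correlation). Cd1d1, which presents lipid antigens, had 162 counts against 1 (ratio 94.975, exact 95% counting interval 16.8 to 3774). The antiviral gene Oasl2 had 101 against 1 (ratio 59.2, 10.4 to 2362) and Gstt1 163 against 1 (ratio 95.6, 16.9 to 3797). Tesc (76 counts against 0) and Ms4a4c (126 against 0, with close relatives and uncertain counts) were at least 14.9-fold and at least 24.6-fold lower, set against 3 counts over the group. Fosl1 (log2 3.51), Fxyd3 (log2 2.95), Ldhb (log2 2.18) and Pstpip2 (log2 2.16) rose. Fosl1 and Fxyd3 were at 384 and 1720 CPM in keratinocyte-like cells of the depleted samples. Keratinocyte markers rose in the Langerhans-like cells (6 of 6, median log2 2.32). In these cells 1 of 9 wound activation genes rose over all genes and 3 adjusted over the list alone (median log2 0.91; adjusted p = 0.181 with an estimated correlation), and 2 of 6 contractile genes fell in both counts (adjusted p = 0.620 with an estimated correlation). Samples held 52 to 166 cells of the class. The count of 198 was 612 without depleted replicate 1, 129 and 96 without depleted replicates 2 and 3, and 79, 91 and 73 without control replicates 1, 2 and 3. It was 13 at clustering resolution 2 and 652 without a filter on low counts, and DESeq2 called 264.

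The remaining classes gave few calls (edgeR, n = 3 each). T, NK or innate lymphoid-like cells had 0 of 9285 genes (783 at an unadjusted p under 0.05, 61 by DESeq2, 56 without depleted replicate 1). Their smallest p-values belonged to the lipid carrier gene Fabp4 (6.69 ± 3.23 against 109 ± 53.8 CPM), Ppp1r14c (6.87 against 44.4) and Serping1 (3.69 against 28.0), each with adjusted p = 0.187 and higher in 3 of 3 depleted samples. Blood endothelial-like cells of the depleted samples held 13687 CPM of Fabp4. Sebocyte-like cells had 0 of 8425 (779, 61 by DESeq2, 20 without depleted replicate 1, 11 without depleted replicate 3), led by Sccpdh (log2 -1.82, adjusted p = 0.256), Lars2 (log2 -1.16, adjusted p = 0.263) and Il1b (log2 -3.10, adjusted p = 0.263). Pericyte or smooth muscle-like cells had 2 higher genes, among them the acute-phase gene Saa3 (18.1 to 850 CPM, log2 5.44, adjusted p = 0.00981, counts uncertain). The count was 0 without control replicate 1, 2 or 3. Adipocyte-like cells of the depleted samples held 17487 CPM of Saa3. Melanocyte-like cells had 3, Krt14 (log2 3.15), Krt5 (log2 2.96) and Fxyd3 (log2 2.29), with a median log2 of 2.87 over 8 keratinocyte markers. The count was 0 without control replicate 1 or 2 or depleted replicate 1 or 2, and 5 without depleted replicate 3. Mast-like cells had 1, Ly6c1 (2 counts against 117, ratio 53.3, exact 95% counting interval 14.4 to 446, adjusted p = 0.00548, counts uncertain). That count was 0 without control replicate 2 or 3 or depleted replicate 2. Blood endothelial-like cells of the depleted samples held 1245.5 CPM of Ly6c1. Without a filter on low counts the calls of these classes, in the order given, were 23, 15, 114, 161 and 12, and when doublets were not removed 13, 2, 7 and 9 in all but mast-like cells. Fcer1g, Csf1r and Tyrobp passed in none of the classes in which they were tested. The lowest adjusted p of Fcer1g was 0.0798 in Langerhans-like cells, where it was higher in 3 of 3 depleted samples (782 ± 30.02 against 1247.5 ± 202 CPM, log2 0.67). In mast-like cells, known for Fcer1g, it was 4686 against 4339 CPM (adjusted p = 0.964).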

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

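The tests of free RNA in the myeloid-marked subcluster, of a wrong label, of the 5 granule genes and all counts over other splits of the samples were chosen only after the results were seen.

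Cluster 25 (820 cells, led by Serpine2, Slc26a7, Igfbp3, Crabp1 and Dkk2, median 2087.5 UMIs) belonged to no class and entered no comparison of the report. It stood out because its share in the lowest depleted sample, 1.425% of cells, lay above that in the highest control sample, 0.949%; the highest depleted share was 2.17%. Of its leading genes, Crabp1, Dkk2, Enpp2 and Wif1 are on the fixed list of papillary and hair follicle fibroblast genes. The loss of macrophage-like cells alone raises the other shares, and no explanation was tested.

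The first pattern is fibroblast-like subcluster 11, led by Lyz2, Cd74, Tyrobp and Fcer1g. Free RNA keeps its genes in 1 ratio, yet 10 keratinocyte markers had a median log2 ratio of -0.29 (95% bootstrap interval -0.37 to -0.02) in the subcluster over the other fibroblast-like cells and Fcer1g 4.80, which argues against it. Doublets of a fibroblast-like and a myeloid cell may account for it, with mixtures of 7.15% to 15.3% myeloid RNA. Observed Fcer1g was 1.14, 1.28 and 1.23 times the predicted level in the control samples and 1.42 times in depleted replicate 3 (median 1.26). It thus lay above the prediction in each of the 4 samples. Within the 3 control samples the cells of the subcluster held a median of 19298, 16434 and 17195 UMIs against 15684, 12556 and 13266. In depleted replicate 3 it was 17514 against 9522.5, at only 7.15% myeloid RNA. Macrophage-like cells held medians of 5802, 5809 and 5329 in the control samples and 9049 in depleted replicate 3. Whether the mixtures match these depths was not tested. A mixture fitted to the subcluster's own profile cannot tell doublets from fibroblast-like cells with myeloid RNA of their own. A signature that only mesenchymal cells show was not settled by the share of control cells with 8 or more pan-myeloid genes. In fibroblast-like cells it was 2.10 times that of keratinocyte-like cells (17 of 3203 against 14 of 5542, 95% interval 1.04 to 4.26). The ratio was 1.19 without control replicate 2 and 4.45 without control replicate 1. The fibroblast-like share was lower in control replicate 1 (0.656% against 0.881%) and higher in replicates 2 (0.520% against 0%) and 3 (0.473% against 0.238%). Such cells were also 2 of 227 sebocyte-like (0.881%), 1 of 159 melanocyte-like (0.629%), 1 of 119 pericyte-like (0.840%) and 1 of 422 blood endothelial-like control cells (0.237%). The fibroblast-like share, 0.531%, lay within the wide 95% interval of each of these classes. Cells this rich in pan-myeloid genes were thus seen in other classes too. Depletion of macrophages, the study's own variable, stays among the open explanations of its lower share in the depleted samples, which both readings allow.

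The second pattern is depleted replicate 1, whose fibroblast-like and keratinocyte-like cells stood apart from those of the other depleted samples. A shift of the whole library is a candidate explanation: its distance to replicates 2 and 3, over the distance between those, was 2.18 in fibroblast-like cells, and the median over the other classes was 0.906 times that. Early-response genes set off by dissociation argue the other way, with a median log2 difference of -0.49 (-1.09 to 0.02) where a rise was needed. A control library with a wrong label is argued against by its macrophage-like share of 0.823%. A deeper depletion or another state of this wound was not tested, and no label gives a batch.

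The third pattern is the 2057 genes called in neutrophil-like cells, deeper in the depleted samples. After thinning to 500 UMIs, 90.4% of these genes (89.1% to 91.7%) kept their sign and at least 0.5 of their log2 fold change and 972 were called. The share itself met the bound of 90% set in advance against depth as the cause, while its interval reached below 90%. Random thinning keeps the expected proportion of each gene in a cell, so fold changes of summed counts largely persist whatever the depth. Fewer calls also follow from fewer UMIs. Neither value can decide, so a contribution of depth stays open. Free RNA may contribute to the 1029 higher genes, of which 10.6% lay at least 3 times above all other cells and 75.9% below them, which leaves it open as well. Ngp, Ltf, Camp, Fcnb and Chil3 stood higher in neutrophil-like cells than in any other class, with a lowest CPM ratio of 2.22. They were picked for the largest rises, and Ngp and Camp also lead the cluster that held most of these cells in the depleted samples. A high ratio was thus partly set by the choice of genes. Yet Ngp stood at 7818 CPM against 24.3 in the highest other class, Ltf at 1092 against 24.0 and Camp at 1545 against 12.6. Free RNA would not exceed its source, so these values argue against free RNA of the other named classes for Ngp, Ltf and Camp. Fcnb (20.2 against 8.82) and Chil3 (5407 against 2439) lay closer to macrophage-like cells, and for them it stays open. Cells in no class were not compared. For these 5 genes, neutrophils at an earlier stage in the depleted wounds are a hypothesis that was not tested.

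The 6 samples make 10 splits into 3 and 3, the real one included, too few for a share under 0.05, and the values are given for that reason only with the highest other split. As many genes were called in 1 split (the real one) in Langerhans-like (198, highest other 3), blood endothelial-like (31 and 0), fibroblast-like (8 and 0), mast-like (1 and 0), macrophage-like (511 and 0), neutrophil-like (2057 and 0) and pericyte-like cells (2 and 0) and for the classes called (3 and 0). It was 2 splits in melanocyte-like cells (3, highest other 6) and all 10 in T, NK or innate lymphoid-like (0 and 0), keratinocyte-like (0 and 5) and sebocyte-like cells (0 and 0) and for subclusters (0 and 0). As many gene lists were called in 1 split in blood endothelial-like (12, highest other 8), 2 in fibroblast-like (15 and 15), 4 in macrophage-like (14 and 16), 4 in neutrophil-like (12 and 13) and 6 in keratinocyte-like cells (10 and 13). For Fcer1g positive against negative cells, swapping the kinds within samples gave as many genes in 1 of 32 ways (21, highest other 18). The real labelling always counts among the 32, so this is the lowest share the swaps allow. The test was also chosen after the results were seen, so it does not exclude chance.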

How the results depend on the processing

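Over 328 comparisons of main results with an alternative, 217 stayed on the same side or within 1.5 times, 106 moved, 3 weakened and 2 reversed; for gene lists it was 687 the same and 130 weaker of 817, and for named genes 1095 the same, 40 stronger and 133 weaker of 1268. Naming clusters by leading genes over all other cells was chosen after seeing the data. The cause was not tested unless stated. The smallest library tested held 45138 UMIs, in mast-like cells, and the smallest of the macrophage-like class 384298.

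Leaving out 1 sample moved the classes called from 1 to 6, the macrophage-like log2 fold change from -4.07 to -2.65, and the genes called from 73 to 612 in Langerhans-like, 0 to 56 in T, NK or innate lymphoid-like, 0 to 132 in blood endothelial-like, 0 to 503 in fibroblast-like, 0 to 10 in keratinocyte-like, 0 to 1 in mast-like, 0 to 5 in melanocyte-like, 47 to 1128 in macrophage-like, 566 to 3419 in neutrophil-like, 0 to 3 in pericyte-like and 0 to 20 in sebocyte-like cells. Lists called ranged from 8 to 14 in blood endothelial-like, 13 to 17 in fibroblast-like, 6 to 10 in keratinocyte-like, 13 to 16 in macrophage-like and 10 to 11 in neutrophil-like cells, subclusters from 0 to 3, genes higher in Fcer1g positive cells from 7 to 29 and lower from 1 to 6, the Fcer1g share difference from -3.11 to -1.65 points and its log2 ratio from -0.52 to -0.11.

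DESeq2 called 61 genes in T, NK or innate lymphoid-like, 163 in blood endothelial-like, 809 in fibroblast-like, 227 in keratinocyte-like, 3 in mast-like, 32 in melanocyte-like, 805 in macrophage-like, 17 in pericyte-like and 61 in sebocyte-like cells. Without a filter on low counts the numbers were 652 in Langerhans-like, 23 in T, NK or innate lymphoid-like, 457 in blood endothelial-like, 14 in fibroblast-like, 2 in keratinocyte-like, 12 in mast-like, 161 in melanocyte-like, 783 in macrophage-like, 114 in pericyte-like and 15 in sebocyte-like cells. With sex as a covariate they were 1 in keratinocyte-like, 11 in melanocyte-like and 4 in sebocyte-like cells. Without doublet removal they were 13 in T, NK or innate lymphoid-like, 55 in blood endothelial-like, 9 in melanocyte-like, 513 in neutrophil-like, 7 in pericyte-like and 2 in sebocyte-like cells, and 381 higher and 249 lower between Fcer1g positive and negative cells. At resolution 0.5 macrophage-like cells had 1107, and at resolution 2 Langerhans-like had 13, melanocyte-like 6, and 1 gene was lower in Fcer1g positive cells, as at 4000 UMIs (1).

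With the estimated correlation 0 lists were called in each class. At least 500 genes and under 10% mitochondrial share gave 1 called class and log2 fold changes of -3.31 in macrophage-like and -1.63 in dendritic-like cells that no longer passed; shares of cells outside the macrophage, dendritic and Langerhans classes also gave 1 class, as the removed classes left that denominator. Naming over all other cells gave 1 called subcluster. Leaving out cells with UMIs of 2 or more pan-myeloid genes gave 5 called genes in fibroblast-like cells, 0 higher and 5 lower in Fcer1g positive cells (5 samples, 185 positive cells, 5286 genes), an Fcer1g share difference of 0.403 points and a log2 ratio of 0.29. This filter selects on the myeloid RNA compared and removed a larger share of control than of depleted cells, so these values decide nothing about the direction. The share difference was -5.91 points without doublet removal and -4.47 at 4000 UMIs.

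The replicate numbers are those of the sample titles, and the deposited files carry other numbers in their names, so the block need not mark a shared animal or day. The numbers did not pair the samples: deviations of same-numbered samples correlated at -0.282, -0.0869 and -0.290, and not every sample correlated best with its own number. With the replicate number as a block the genes called were 0 in fibroblast-like, 73 in blood endothelial-like, 0 in melanocyte-like, 153 in macrophage-like, 1220 in neutrophil-like and 6 in pericyte-like cells.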

Other observations

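Cluster 35 (233 cells) was led by simple-epithelium genes Krt8, Krt18 and Krt19 with Wfdc2 and Csn3, a casein gene of the mammary gland. It made up 0.908% of cells in control replicate 1 and 1.27% in depleted replicate 3, the 2 samples labelled female, and 0 cells in the other 4.

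Cluster 21 (1146 cells, median 643 UMIs) was led by Elane, Prtn3 and Mpo, the azurophil granule genes of early neutrophil precursors, with the proliferation genes Ube2c and Birc5. It stood at 0.988% to 2.63% of cells over all 6 samples and stayed in no class.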
